A study of Homo sapiens with 3 samples.

How the data were processed

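Gene expression was measured in H9 human embryonic stem cells, an established pluripotent line, with 6 single-colour Illumina bead arrays, 2 for each of 3 sample types. Per the labels' protocols, total RNA was purified on columns with DNA digestion, 400 ng entered a linear amplification with 7 h of in vitro transcription, and the product carried Cy3. The series design text describes the arrays of a sample type as biological replicates. The replicate numbers came from the file headers, because the sample labels carry none.

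Each array file held 24354 probes with 3 values per probe. Per the file headers, the first was the average signal, an intensity on a linear scale, and the second was the spread among the beads of the probe in the same intensity unit. The third value, also per the file headers, was a detection score between 0 and 1, high where a probe was brighter than the negative controls. BeadStudio 1.5 made these values, per the submitters' processing notes. The deposited signals were neither background-subtracted nor normalized between arrays, as their values showed: the lowest lay between 135.5 and 161.3 units, and the array medians ranged from 254.3 to 287 units. A separate deposited table gave the authors' processed intensity, 1 background-subtracted value per sample type rounded to whole units. That table was blank for 41.1% to 41.3% of the probes, its lowest value was 26, and its column medians were 357 for UM, 359 for MEF-CM and 360 for UM_GTA. Its values had slopes of 1.00, 1.02 and 1.05 against the mean signals of the arrays, and its normalization is not given in the sources used here. It was used only to compare directions.

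The signals were background-corrected, quantile-normalized and log2-transformed with the neqc function of limma 3.58.1 in R 4.3.3. The function inferred the mean and spread of the negative controls from the detection p, taken as 1 minus the deposited score, and added an offset of 16 units. A probe was kept when its detection p was under 0.05 on both arrays of at least 1 sample type. The 4 control probes were left out after normalization. This left 12584 probes, of which 10244 carried the suffix S, 1427 the suffix A and 913 the suffix I. Of these, 11214 were detected on all 6 arrays.

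A linear model with 1 mean per sample type was fitted to all 6 arrays, so that the 3 comparisons shared an estimate of the spread with 3 residual degrees of freedom. The variances were moderated by limma's empirical Bayes step without an intensity trend, which gave 2.49 prior degrees of freedom. All p-values of single probes come from this limma test and are two-sided, and adjusted p-values are Benjamini-Hochberg values over the 12584 probes within a comparison. The threshold was an adjusted p under 0.05. A called probe has an adjusted p below that value. Errors of fold changes are standard errors of the model, intervals are 95% confidence intervals, and SD values are over the 2 arrays of a sample type.

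The correlation of the responses to both re-stimulations was set beside 100 simulated pairs of unchanged groups that shared the UM arrays. Where no array of a sample type detected a probe, its fold is a lower bound. For that bound, the dim level on each array was the higher of the probe's own value and the lowest value among detected probes.

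The same functions were tested on simulated data with 200 changed probes in a simulated MEF-CM against UM comparison, which kept 13020 probes. The test recovered 1.49% of the probes changed 1.5-fold, 32.8% of those changed 2-fold and 65.2% of those changed 4-fold. Of 72 simulated calls, 6 were unchanged probes.

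The tests of the 3 comparisons and of the correlation, the sample grouping, the filters, the thresholds, the rule for named items and most alternatives were chosen before the data were examined. The alternatives covered the background correction, the normalization, the floor, the detection filter, the variance model, the threshold, the arrays in the fit and leaving out each array in turn. The replicate block, the use of a separate UM array for each response, the simulated overlap of calls and the partitions of the arrays into other pairs were added after the data were examined. So were the spread by brightness, the question of a medium change, the look at a probe with disagreeing replicates, the isoform pairs and the same-sign shares.

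The probe IDs are record numbers with a suffix, and the files do not pair them with genes. The gene table used here, of the human RefSeq annotation, holds 0 lines with such a number, so no probe is given a gene name. The naming rule would have taken, per comparison, the 10 named genes with the largest rise and the 10 with the largest fall among those past the threshold whose arrays did not overlap between the sample types, together with fixed genes and list members. It was applied to probe IDs in MEF-CM against UM, and only the first 2 in each direction are printed. The tests of gene lists, the cell type markers and the fixed genes need gene names and were not run.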

Results

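The study followed the early transcriptional response of H9 human embryonic stem cells to the return of self-renewal signals. Cells of this established line were grown for 3 days in medium conditioned by mouse embryonic fibroblasts (MEF-CM), which carries factors secreted by the fibroblasts. A starvation period of 1 day in unconditioned medium (UM) followed. UM cells without re-stimulation were the control. The other cells were re-stimulated for 4 h with MEF-CM or with UM_GTA, unconditioned medium with the defined additions Activin A, TGFß1 and Gremlin. The concentrations were 20 ng/ml of Activin A, 2 ng/ml of TGFß1 and 200 ng/ml of Gremlin. Activin A and TGFß1 are ligands of the TGF-beta superfamily, and Gremlin is a secreted antagonist of bone morphogenetic proteins. The growth factor FGF2 was present at 10 ng/ml in UM and UM_GTA and at 5 plus 5 ng/ml in MEF-CM.

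Each sample type was represented by 2 arrays. Between 12483 and 12774 of the 24354 probes were detected per array, or 51.3% to 52.5%. The median signal was 1.21 to 1.23 times the mean background, and the upper quartile was 3.15 to 3.49 times the background. The replicate arrays correlated at r = 0.993 to 0.994 across probes, and arrays of different sample types at r = 0.991 to 0.993. Probes are not independent replicates. The first principal component held 29.7% of the variance and placed the UM arrays at -13.7 and -14.7 and the 4 re-stimulated arrays between 4.64 and 13.4. The second component held 23.3% and separated the re-stimulations. It placed the MEF-CM arrays at -15.2 and -8.64 and the UM_GTA arrays at 10.4 and 9.67, with UM between them at 2.89 and 0.927. The third held 17.6% and did not follow the sample types. It set the UM_GTA replicates apart from each other, at -14.9 and 12.1, with the other arrays between -1.76 and 3.97. The small number of arrays limits the precision of every value, with a median standard error of 0.10 for a log2 fold change.

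The first comparison asked which transcripts responded within 4 h when starved cells received MEF-CM again. The labels describe no cells given fresh UM for 4 h. Effects of MEF-CM therefore cannot be told apart from a change of medium or a later collection. In MEF-CM, 18 probes were higher and 4 lower than in UM. The largest rise among them was that of GI_31077201-S, which was 5.31-fold higher in MEF-CM in the main setting. GI_27436943-S was 4.94-fold higher. GI_31542304-S fell 3.24-fold and GI_23308518-S fell 2.71-fold. These 4 IDs are printed without gene names because the files do not pair them with genes.

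The normalized signal of GI_31077201-S was 7.18 ± 0.15 in UM and 9.59 ± 0.23 in MEF-CM (log2, mean ± SD, n = 2 arrays each). The log2 fold change was 2.41 with a standard error of 0.14 and a limma adjusted p of 0.0118. GI_27436943-S stood at 13.36 on both UM arrays and at 15.67 ± 0.013 in MEF-CM, a log2 fold change of 2.31 with a standard error of 0.068 and an adjusted p of 0.00168. GI_31542304-S dropped from 9.73 ± 0.14 to 8.03 ± 0.16, a log2 fold change of -1.70 with a standard error of 0.13 and an adjusted p of 0.0308. GI_23308518-S dropped from 10.27 ± 0.099 to 8.83 ± 0.083, a log2 fold change of -1.44 with a standard error of 0.092 and an adjusted p of 0.0149. All 4 probes were detected on all 6 arrays, and both MEF-CM arrays lay on the same side of both UM arrays.

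**Figure D1:**
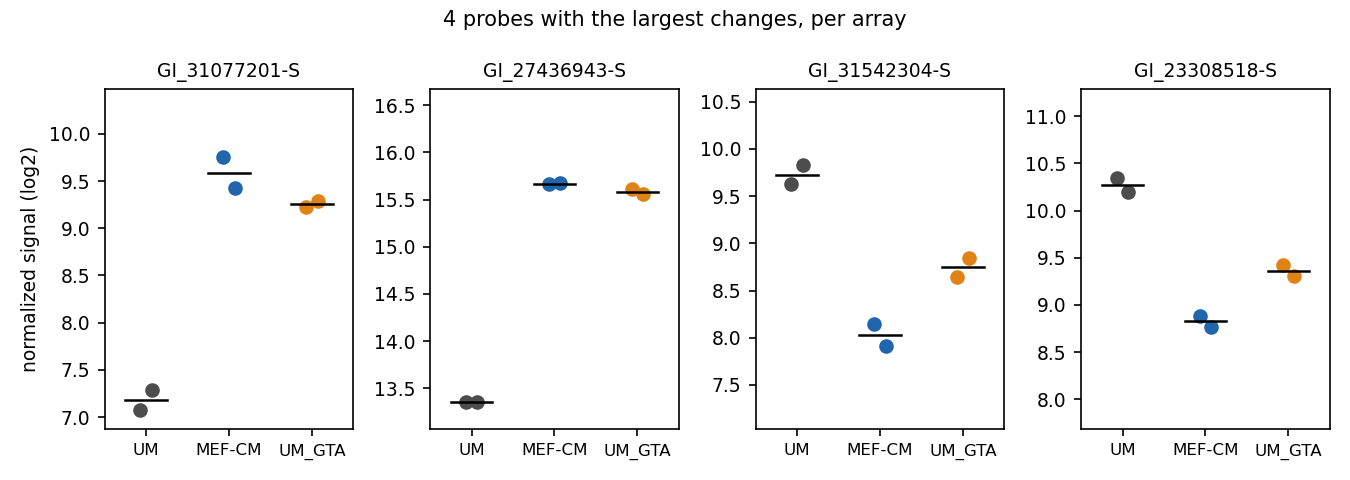
Normalized signal (log2) of the 4 named probes in each sample type. Points are single arrays, 2 per sample type, horizontal lines are their means, and the vertical axes have the same length in log2 units but different starting points. The MEF-CM points of GI_27436943-S sit at 15.66 and 15.68 against 13.36 in UM, and the UM_GTA points of both falling probes sit between those of UM and MEF-CM.

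The 20 called probes detected in both sample types had fitted changes of at least 0.84 on the log2 scale. The median size over all 22 was 1.26, also with the other 2 at their bounds. In all 22, both MEF-CM arrays lay on one side of both UM arrays. Over all 12584 probes, the arrays did not overlap for 5104, or 40.6%, where chance gives 33.3%, with 2441 higher and 2663 lower in MEF-CM. By suffix, 16 called probes were of class S, 4 of class A and 2 of class I. For the 2 called probes not detected in both sample types, which rose, UM was below detection on both arrays, and the rises were at least 1.72-fold and at least 1.12-fold. An unadjusted p under 0.05 was reached by 1243 probes, 653 higher and 590 lower in MEF-CM, where 629 would be reached by chance. A change of at least 2-fold was fitted for 37 probes, of which 16 were called.

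Rising probes made up 81.8% of the calls, against 71.6% when the deposited signals were only log2-transformed and 65.9% without background correction at an offset of 50 in place of 16 units, while over all probes with an unadjusted p under 0.05 or non-overlapping arrays the split was close to even. The log2 fold change of GI_31077201-S was 1.35 with that same change of correction and offset. The number of calls rose to 185 with an intensity trend in the variance model and fell to 0 or 1 when any 1 of the 6 arrays was left out.

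The second comparison asked which transcripts responded within 4 h to the defined mixture. In UM_GTA, 18 probes were higher and 2 lower than in UM. A change of medium or a later collection cannot be told apart from the defined mixture here either. GI_31077201-S was 4.22-fold higher and GI_27436943-S 4.67-fold higher than in UM, and both passed the threshold. GI_31542304-S and GI_23308518-S had lower means than in UM but did not pass it. With an intensity trend they did, at limma adjusted p of 5e-05 and 6.81e-06. Without a detection filter they did not, at 0.319 and 0.23. Their lowest adjusted p-values, 1.6e-08 and 4.87e-09, came from the deposited signals only log2-transformed, a setting without normalization between arrays.

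GI_31077201-S reached 9.26 ± 0.041 in UM_GTA (log2, n = 2 arrays), a log2 fold change of 2.08 with an adjusted p of 0.0163. GI_27436943-S reached 15.59 ± 0.033, a log2 fold change of 2.22 with an adjusted p of 0.00205. The log2 fold change of GI_31542304-S was -0.98, with a standard error of 0.13 and an adjusted p of 0.0998. That of GI_23308518-S was -0.90, with a standard error of 0.092 and an adjusted p of 0.0602. The arrays of UM_GTA and UM did not overlap for either probe.

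The 19 called probes detected in both sample types had fitted changes of at least 0.77 on the log2 scale and ranged from -1.37 to 2.26. The median size over all 20 was 1.14, also with the other probe at its bound. Class S held 16 of them and class A held 4. The called probe not detected in both sample types, which fell, was below detection on both UM_GTA arrays and was at least 1.04-fold lower there. An unadjusted p under 0.05 was reached by 1470 probes, 777 higher and 693 lower in UM_GTA, against 629 by chance. The arrays did not overlap for 42.4% of the probes, 2509 higher and 2822 lower, against 33.3% by chance. Rising probes made up 90% of the calls, against 75% with log2-transformed deposited signals and 74.9% without background correction at an offset of 50 units. The number of calls was 228 with an intensity trend, 10 with median scaling of the arrays, and 0 to 2 when any 1 array was left out.

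Both re-stimulations were then set side by side, since the design placed a complex conditioned medium and a defined mixture against the same starved cells. The same 14 probes rose in both, among them GI_31077201-S and GI_27436943-S. Independent lists of this size would share 0.026 rising probes. No falling probe was called in both, where independent lists would share 0.00064. The called probes numbered 28 in all, 22 higher and 6 lower than in UM, and all 28 had fold changes of the same sign in both re-stimulations. Over all probes the signs were the same for 67.3%, against a mean of 66.7% and at most 67.5% in simulated unchanged groups that shared the UM arrays.

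In the 14 shared probes the log2 response to UM_GTA was 77.6% to 134% of the response to MEF-CM, with a median of 94.7%. The 22 probes called in MEF-CM had a median fitted response in UM_GTA of 90.3% of that in MEF-CM. The 20 probes called in UM_GTA had a median fitted response in MEF-CM of 97.3% of that in UM_GTA. The choice of probes can lower the last pair of medians, and the noise of the shared UM arrays can bring all of these percentages closer to 100%. With a separate UM array for each response, added after the data were examined, the median over the 14 was 93.6% and 100% in the 2 assignments. All 28 signs were again the same, but that outcome was fixed in advance. For each of the 28, the arrays of either re-stimulation lay on one side of both UM arrays. The probes had been chosen with both UM arrays, so part of the overlap may come from those arrays. In 100 simulated pairs of unchanged groups that shared the UM arrays, no probe was called the same way in both, but these lists held at most 1 and 2 calls and so set no value for lists of 22 and 20. The 14 shared calls became 0 when any 1 of the 6 arrays was left out and ranged from 2 to 106 over the other alternatives.

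**Figure D2:**
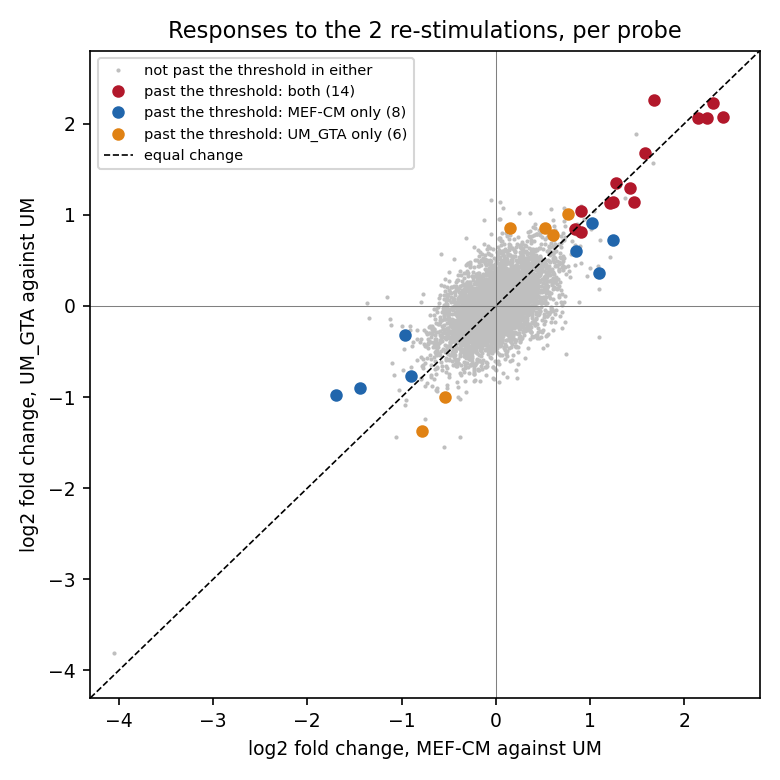
Log2 fold change against UM of each of the 12584 kept probes in MEF-CM (horizontal axis) and UM_GTA (vertical axis). Coloured points passed the threshold in both re-stimulations (14), in MEF-CM only (8) or in UM_GTA only (6), grey points in neither, and the dashed line marks equal change. The isolated grey point at -4.05 and -3.81 is a probe with disagreeing replicates.

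Across the 12584 probes the log2 fold changes of both re-stimulations had a Pearson correlation of 0.579 and a Spearman correlation of 0.478. Simulated unchanged groups that shared the UM arrays gave a mean Pearson correlation of 0.498 with a highest value of 0.606, and a mean Spearman correlation of 0.451 with a highest value of 0.471. The covariance was 0.0279, against a simulated mean of 0.014 and a highest simulated value of 0.0205, which left a difference of 0.0138. With a separate UM array for each response, chosen after the data were examined, the Pearson correlations were 0.225 and 0.251, against at most 0.095 in simulated unchanged groups. These correlations are across probes, which are not independent replicates. Each simulated probe had its own fitted spread, and the probe with disagreeing replicates was kept. That probe can widen the simulated ranges of the Pearson correlation and the covariance, and values without it were not computed.

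The direct comparison asked whether the defined mixture and the conditioned medium gave different responses. No probe passed the limma threshold between UM_GTA and MEF-CM, and the smallest adjusted p was 0.213. The fitted differences ranged from -1.43 to 1.40 on the log2 scale. An unadjusted p under 0.05 was reached by 1264 probes, 645 higher and 619 lower in UM_GTA, against 629 by chance. The arrays did not overlap for 42.1% of the probes, 2593 higher and 2711 lower in UM_GTA, against 33.3% by chance. Neither measure was clearly lower than against UM, where the counts were 1243 for MEF-CM and 1470 for UM_GTA and the shares 40.6% and 42.4%. The lack of calls therefore does not show that the re-stimulations were alike. With an intensity trend in the variance model 71 probes passed, 48 of them higher in UM_GTA.

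GI_31077201-S differed by -0.33 (95% interval -0.67 to 0.01) and GI_27436943-S by -0.08 (-0.25 to 0.09) between UM_GTA and MEF-CM on the log2 scale. The difference was 0.72 (0.39 to 1.04) for GI_31542304-S and 0.53 (0.30 to 0.76) for GI_23308518-S, with higher values in UM_GTA. Their adjusted p-values of 0.28 and 0.276 did not pass. Over 17 alternatives these ranged from 0.00629 to 0.588 and from 0.00967 to 0.653, lowest with the intensity trend. All the probes named here were chosen for large changes in MEF-CM against UM. That choice alone can make their responses in UM_GTA look weaker, so these intervals are not independent evidence of a difference. Among all 28 probes called against UM, the fitted response was larger in MEF-CM for 17 and larger in UM_GTA for 11.

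The 8 probes called in MEF-CM only had a median response in UM_GTA of 60.4% of that in MEF-CM. The 6 called in UM_GTA only had a median response of 169% of that in MEF-CM. The 95% interval of the difference excluded 0 for 6 of the 8, for 5 of the 6 and for 2 of the 14 called in both. These counts and medians include 3 probes that were below detection in at least 1 sample type. Without them the interval excluded 0 for 4 of 6, 4 of 5 and 2 of 14, and the medians of the first 2 sets were 60.4% and 164%. These probes were chosen on the same arrays, so the intervals are not independent evidence of a difference. The median distance from the estimate to the interval's edge was 0.22 on the log2 scale.

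**Figure D3:**
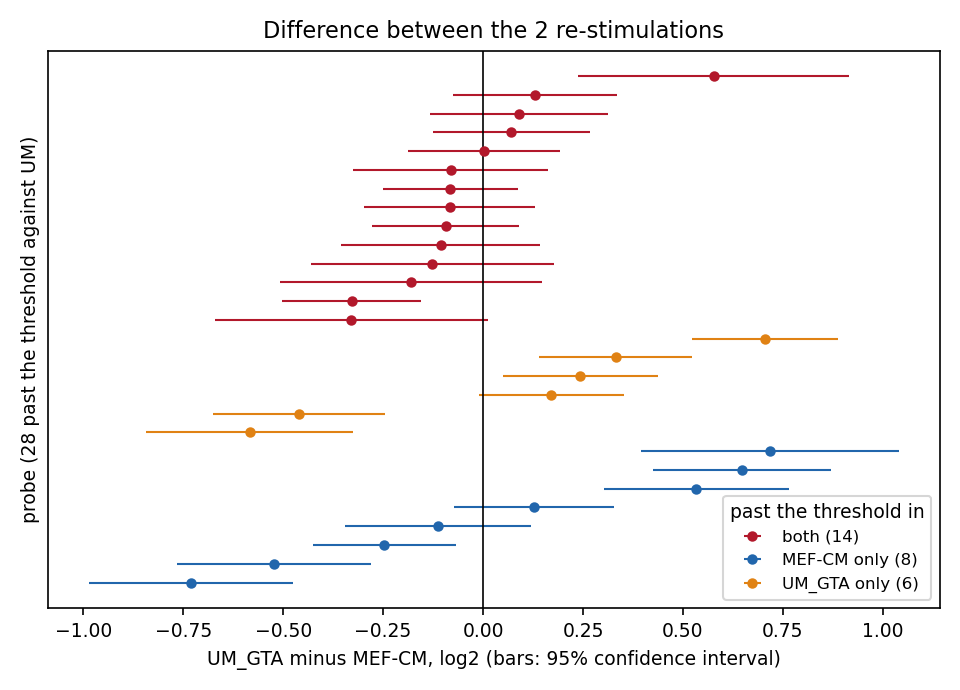
Difference between the re-stimulations (UM_GTA minus MEF-CM, log2) for the 28 probes called against UM. Points are fitted differences, bars are 95% confidence intervals, and colours give the re-stimulation in which the probe was called. Bars exclude 0 for 13 of the 28 probes, and for 10 of the 25 detected in every sample type.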

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

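The replicate block and the separate UM arrays were chosen only after the main results were seen, and the other alternatives before. In the order MEF-CM against UM, UM_GTA against UM and UM_GTA against MEF-CM, the main counts of called probes were 22, 20 and 0. They were 81, 76 and 10 with the deposited signals log2-transformed only, 176, 243 and 76 without background correction at an offset of 50 units, and 185, 228 and 71 with an intensity trend. The first of these settings had no normalization between arrays. Its smallest limma adjusted p in MEF-CM against UM was 1.97e-122. A value that small from 6 arrays needs a nearly common spread for all probes, so its p-values call for caution. The first 2 counts were 9 and 9 with background subtraction and a floor of 5 units, 6 and 4 without a detection filter, 3 and 2 at an adjusted p under 0.01, and 2 and 3 with only the 4 arrays compared. The MEF-CM and UM_GTA counts were 22 and 10 with median scaling, 25 and 10 with a floor of 50 units, and 30 and 36 among probes detected on all 6 arrays. Leaving out 1 array gave 0 to 1 calls in MEF-CM, 0 to 2 in UM_GTA and 0 between them, with the lone array assumed to vary like the other groups. Same-numbered arrays did not deviate together (r from -0.021 to 0.0073), and the replicate block gave 8, 5 and 0 calls, 7 and 4 of them among the main calls. Robust moderation and an added 1.5-fold minimum left 22, 20 and 0. Leaving out 1 array also left fewer residual degrees of freedom and 1 sample type with a single array. The lost calls therefore cannot be read as results that hang on that array. Except for the stricter threshold and, in part, the intensity trend, where the spread fell with brightness, the cause of the shifts was not tested. The log2 fold changes of the 4 named probes against UM kept their sign under the 17 alternatives run for each, and GI_31077201-S, GI_27436943-S, GI_31542304-S and GI_23308518-S passed in MEF-CM under 10, 13, 7 and 9 of them and in UM_GTA under 9, 13, 3 and 4. The change of GI_31077201-S ranged from 1.35 to 2.57 in MEF-CM and from 1.11 to 2.20 in UM_GTA, lowest without background correction at the offset of 50. The 14 probes shared by both re-stimulations became 2 at an adjusted p under 0.01, 3 with the block, 3 without a detection filter, 9 with median scaling, 106 with the trend and 0 without any 1 array. The authors' deposited table gave the same direction for the 21 of 22 called probes in MEF-CM and the 19 of 20 in UM_GTA for which it held both values. Its values followed the mean signals of the same arrays (r of at least 0.9999), so the shared direction is not independent support. The correlation of the responses was 0.706 and 0.699 without 1 of the UM arrays, and 0.443 to 0.502 without 1 of the re-stimulated arrays. It was 0.967 over the 9 probes past an F-test, which were chosen for their differences, and 0.225 and 0.251 with separate UM arrays. Gene list tests, a chip block and a filter on gene symbols were not run, because they need gene names or chip names, and quantile normalization and the removal of control probes were already part of the main setting. The median signal of 1.21 to 1.23 times background limits what can be said of dim probes.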

Other observations

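The spread by brightness, the partitions of the arrays, the separate UM arrays, the simulated overlaps, the medium change, the probe with disagreeing replicates and the isoform pairs were tests chosen only after the main results were seen. With the intensity trend, 124 probes were higher and 61 lower in MEF-CM than in UM, and 173 were higher and 55 lower in UM_GTA. Of these, 86 rose in both and 20 fell in both, where independent lists would share 1.7 and 0.27. Simulated unchanged groups sharing the UM arrays gave lists of at most 3 calls, too short to set a value for the overlap of lists of 185 and 228. Part of this overlap may come from the shared UM arrays. In the main test no falling probe was shared. Of the 71 probes that differed directly between the re-stimulations, 19 were called against UM in MEF-CM only, 24 in UM_GTA only, 6 in both the same way, 1 in both in opposite ways and 21 in neither.

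Illumina's suffix A marks a probe for all isoforms of a gene and the suffix I an isoform-specific one. For 159 records both kinds were kept. Their log2 fold changes correlated across pairs at r = 0.0546 in MEF-CM, 0.0854 in UM_GTA and 0.206 between the re-stimulations. Few of the kept probes passed the threshold, so these low correlations do not show that the probes of a pair responded differently. The ratio of the pair changed past the limma threshold for 0 pairs in any of the 3 comparisons, and an unadjusted p under 0.05 was reached by 8, 13 and 11 pairs, against 7.95 by chance.

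The lowest fitted fold changes of all belonged to GI_41406065-A, singled out after its values were seen, at -4.05 in MEF-CM and -3.81 in UM_GTA with adjusted p of 0.731 and 0.641. Its deposited signal was 7622 and 5215 units on the UM arrays, 233.0 and 3947 on the MEF-CM arrays, and 3631 and 255.0 on the UM_GTA arrays. It was undetected on 1 array of each re-stimulated type and bright on the other 4. It was the 1 kept probe whose replicates differed by over 2 log2 units, by 6.72, where the next probe differed by 1.81.

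The first pattern is that most called probes rose, 18 of 22 in MEF-CM and 18 of 20 in UM_GTA. At an unadjusted p under 0.05 the split was 653 to 590 and 777 to 693, and among non-overlapping probes 2441 were higher and 2663 lower, and 2509 higher and 2822 lower, so the pattern covers the called probes and not the wider sets. Between-array normalization as the whole cause would bring the rising share to 50% or less in some setting, but the lowest share among the other normalizations and without background correction at an offset of 50 units was 65.9%. Dim probes near the background as the cause would remove the excess among probes detected on all 6 arrays, where at least 80% of the calls still rose. Of the main calls, 20 of 22 in MEF-CM and 19 of 20 in UM_GTA were also called there. The filter could therefore hardly change the share, and this test decides little. The dimmest 4195 probes held only 3 main calls in each comparison. What set the direction of the calls stays open, and no biological explanation was tested.

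The second pattern is the likeness of both responses. Noise of the shared UM arrays as the whole cause would leave a correlation of at most 0.095 with separate UM arrays, but the lower of both values was 0.225. A deviation common to both UM arrays would pass that test and stays open. A change of medium or a later collection could also underlie the 14 probes that rose in both, and these cannot be told apart from the added factors. The labels describe no cells given fresh unconditioned medium for 4 h, and do not say whether the control received fresh medium or when it was collected. The probes past an F-test over the sample types numbered 9, against at most 6 in the other partitions of the 6 arrays into pairs, and 1 of the 15 partitions, the real one, gave as many. That number of partitions is too small for a share under 0.05.

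The third pattern is the large gain in calls with an intensity trend. The median spread between replicates was 0.209 in the 4195 dimmest probes and 0.0638 in the 4195 brightest, a ratio of 3.28, where a ratio under 1.2 would have argued against an effect of brightness. A candidate explanation is that a single prior spread is too wide for bright probes, so that real differences between UM_GTA and MEF-CM may be among the 71 calls. The trend also raised the prior degrees of freedom from 2.49 to 15.2, which can itself lower p-values. How much of the gain came from brightness and how much from this rise was not tested. With the trend, 294 probes passed the F-test, against at most 100 in the other partitions, and again 1 of 15 gave as many, too few partitions for a share under 0.05. The highest other partition kept the UM arrays together, and the partitions that separated them gave at most 3 probes.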
